A study of Homo sapiens with 5 samples.

How the data were processed

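Gene expression was measured on Affymetrix whole-transcript arrays in 5 stable clones of Nalm6, an established human cell line of B-cell precursor acute lymphoblastic leukaemia. Of these, 2 clones expressed a nonsense short hairpin RNA (shRNA) and 3 clones expressed a shRNA against MondoA, with 1 array per clone. Per the labels, the cells were grown in medium with 20% serum and 200 mg/dl glucose, and 200 ng of RNA was labelled with biotin as sense-strand target.

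The authors summarised the probes with RMA (robust multi-array average) in Affymetrix Expression Console 1.1, and the deposited values are in log2 units, 1 per probe set. RMA subtracts background, makes the distributions of the arrays equal and combines the probes of a probe set by median polish. The base of the logarithm is not stated in the labels. It was taken as 2, which is what RMA gives, and every log2 difference and fold below rests on that. The values of 33297 probe sets ran from 1.42 to 13.3. None was missing and no filter was apparent. No detection calls and no unsummarised probe intensities were used here, so whether a dim gene was detected was not assessed, and array dates or batches could not be compared. The number of arrays limits the precision.

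Gene symbols and Entrez numbers came from the annotation of the array platform. Exactly 1 symbol was given for 19460 probe sets, several for 1754 and none for 12083, and the latter 2 kinds were left out. Of the 19460, 19429 matched a current gene by Entrez number in a RefSeq table of assembly GRCh38.p14, which was used for names, for the chromosome of each gene and for the order of neighbouring genes. The build behind the authors' annotation is not stated, so no coordinates are given. Where a gene had more than 1 probe set (769 genes), the probe set with the highest mean over all 5 arrays was kept, which left 18417 genes.

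The groups followed the clone labels. Each gene was compared by limma 3.58.1 in R 4.3.3 with a linear model and empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are MondoA shRNA minus control shRNA. Before the data were examined, 31 gene lists with 740 different genes were fixed (673 measured), covering MondoA and its network, metabolism, stress responses, B-cell stages, other cell types, cell cycle, apoptosis, p53, ribosomes, histones, interferon, adhesion and RNA interference. Lists with at least 5 measured members were tested with camera from limma, with a preset correlation of 0.01 and adjustment over the 31 lists. Camera with the correlation estimated for each list, camera on ranks and fry (which tests a list without comparing it with other genes) were alternatives.

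The rule for named genes was also fixed beforehand. It takes MLXIP, TXNIP and ARRDC4, then the 10 genes with the largest rise and the 10 with the largest fall past the adjusted threshold with every MondoA shRNA array outside the control range. Where fewer than 10 passed, genes at unadjusted p under 0.05 with the same separation filled the places and are given as values that did not pass. The rule also takes up to 2 members with the lowest p of each list that passed the list test. Genes named outside the rule are marked as chosen after their values were seen.

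The replicate numbers are shared by the titles of both groups but nothing in the labels links clones of the same number, so they were not used as pairs. A fit with the number as a block was an alternative. Further alternatives left out each array in turn, kept the brighter genes alone, normalised or centred the arrays again, changed the prior variance of limma, weighted the arrays (statmod 1.5.0), tested all probe sets, averaged the probe sets of a gene, dropped the moderation, changed the threshold or asked for an absolute log2 difference of at least 1. Alternatives that left out genes with values shared exactly between arrays, or genes on chromosome 18, were chosen after seeing the data, as was the comparison by chromosome, which used genes with a mean level above 5.

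The limma and camera steps were tested on simulated data built from the means and residual spreads of the 18417 genes, with 200 changed genes in each of 20 simulations. At an adjusted p under 0.05 the limma step called 62.1% of simulated changes of 1 log2 unit, 94.9% of those of 3 log2 units and 0.0837% of unchanged genes. Over all simulations there were 364340 unchanged genes against 2000 changed genes of each size. The share of false calls among all calls is therefore well above 0.0837%. At an unadjusted p under 0.05 in limma stood 6.12% of unchanged genes. The oxidative phosphorylation list, raised by 0.5 log2 units, was called in 20 of 20 simulations, and no list was called in data without a shift. It was the only list shifted and, with 44 measured genes, the longest of the 31. The largest real list median was -0.26 (p53 targets), so the 20 of 20 does not describe shorter lists or smaller shifts. The simulated genes varied independently of each other, which real genes do not. Their spreads include those of genes with tied values, so these shares do not describe the genes that differed most in the real arrays, of which 0 of 40 with an absolute log2 difference of at least 1 passed.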

Results

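The arrays compared Nalm6 clones carrying a nonsense shRNA (2 clones, 1 array each) with clones carrying a shRNA against MondoA (3 clones, 1 array each). MondoA, encoded by MLXIP, is a transcription factor that pairs with MLX and responds to glucose metabolites. The series asks, by its title, how MondoA affects metabolism, differentiation and survival in this leukaemia. All values are RMA expression on the log2 scale, and errors are SD over n = 2 control and n = 3 MondoA shRNA arrays unless another is named.

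The first question was whether the shRNA lowered its target. No difference in MLXIP RNA was detected between the groups. The MLXIP probe set (7959361, gene on chromosome 12) read 6.42 in both control arrays and 6.42, 6.47 and 6.29 in MondoA shRNA arrays 1, 2 and 3. The difference was -0.03 ± 0.06 (SE), with a 95% interval from -0.21 to 0.16 and an adjusted p of 0.959 by limma, and it was 0.03 without MondoA shRNA array 3. The 3 clones are therefore called the arrays labelled MondoA shRNA, and directions below refer to that label. TXNIP, the best known glucose-induced target of MondoA, read 8.96 ± 0.10 in control and 8.86 ± 0.09 in MondoA shRNA arrays, a difference of -0.10 (adjusted p = 0.833). Its relative ARRDC4 read 4.65 ± 0.07 and 4.57 ± 0.05, a difference of -0.08 (adjusted p = 0.833). The list of 17 genes reported as targets of MondoA or its paralogue ChREBP had a median difference of 0.01, with 10 members above 0 and 6 below (camera adjusted p = 0.828). RGS16, a regulator of G-protein signalling, had the largest difference in that list at -1.24, which did not pass the test for single genes. The network of MondoA, MYC, MAX and MLX (13 genes) had a median difference of 0.00.

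The second question was which genes separated the clones. The largest measured difference was in SAMHD1, a phosphohydrolase that degrades deoxynucleotides, which read 3.86 ± 0.40 in control and 7.02 ± 0.25 in MondoA shRNA arrays, a difference of 3.17. The calcium-binding protein gene S100A16 read 3.25 ± 0.02 and 6.04 ± 0.27, and PRPS2, a synthetase that feeds nucleotide synthesis, read 3.87 ± 0.21 and 6.11 ± 0.40. Higher values were also found for the immunoglobulin joining chain gene JCHAIN (difference 1.65), the Toll-like receptor relative CD180 (1.52), the Fc receptor-like gene FCRLA (1.42) and the inhibitory co-receptor gene CD22 (1.27). TASL, an adaptor of endolysosomal Toll-like receptors, differed by 1.76, the endolysosomal exonuclease gene PLD4 by 1.52 and the adhesion molecule gene ICAM3 by 1.47. In the other direction, the receptor tyrosine phosphatase gene PTPRM on chromosome 18 read 5.12 ± 0.01 in control and 2.60 ± 0.11 in MondoA shRNA arrays, a difference of -2.52. Detection above background was not assessed. Where only 1 group's mean lies below the median gene level of 4.15, the difference is a lower bound on the change in RNA if that level is background. In this paragraph that holds for SAMHD1, S100A16, PRPS2, TASL, JCHAIN, CD180 and ICAM3 in control and PTPRM in MondoA shRNA arrays. GZMK, named in the next paragraph, read 3.93 ± 0.18 in control and 2.50 ± 0.14 in MondoA shRNA arrays. As both means lie below that level, its difference may not reflect a change in RNA.

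Lower values were also found for the metalloprotease gene ADAMTS9 (-1.80), the deubiquitinase gene OTUD1 (-1.66), DDIT3, which encodes the stress-induced factor CHOP (-1.53), the granzyme gene GZMK (-1.43), the lectin gene CLEC14A (-1.42), the Rab GTPase gene RAB31 on chromosome 18 (-1.41), the non-coding RNA gene LINC02363 (-1.36), the growth factor receptor gene PDGFRA (-1.34) and RGS16 (-1.24). None of these 20 genes passed the adjusted threshold in limma. The lowest adjusted p of any gene was 0.110, shared by IDH2, PTPRM and SPINT2, of which the mitochondrial enzyme gene IDH2 differed by -0.38 and the protease inhibitor gene SPINT2 by -1.15. IDH2 and SPINT2 were chosen after their values were seen.

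**Figure D1:**
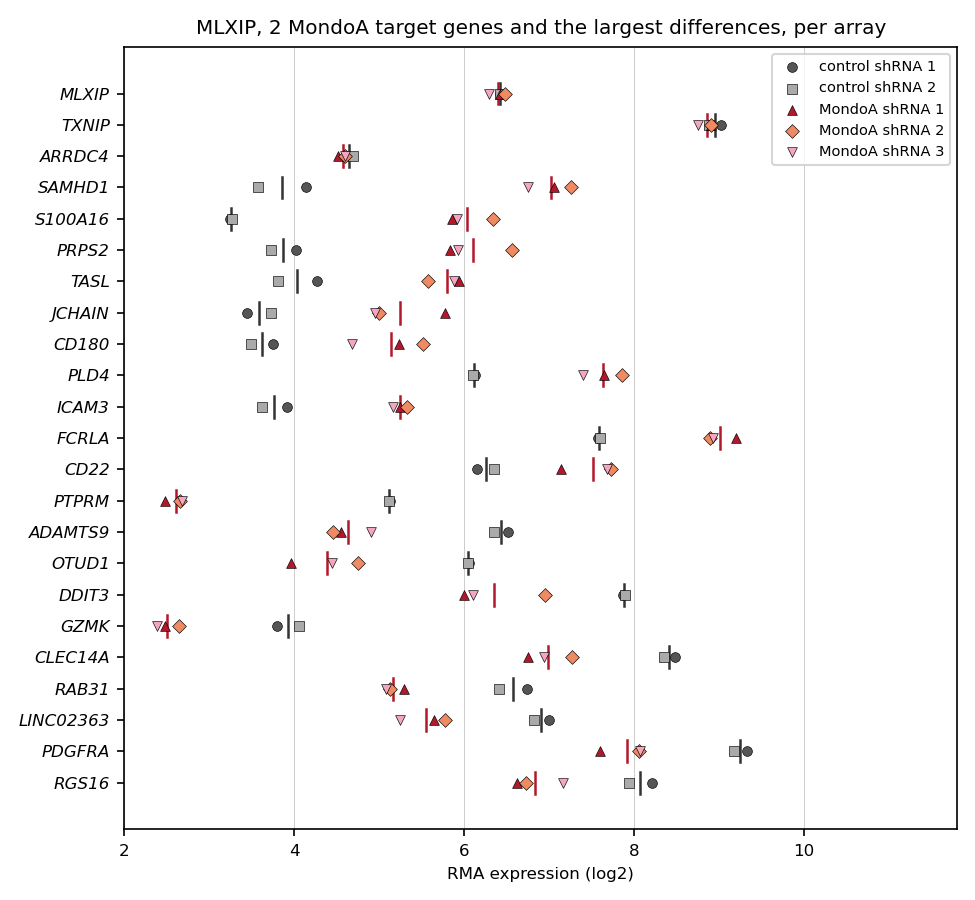
RMA expression (log2, horizontal axis) of MLXIP, TXNIP, ARRDC4 and the genes with the largest differences (vertical axis) in each of the 5 arrays, with short dark lines at the mean of the 2 control arrays and short red lines at the mean of the 3 MondoA shRNA arrays. MLXIP sat between 6.29 and 6.47 in every array, whereas SAMHD1 differed by 3.17 and PTPRM by -2.52 between the group means.

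Across all 18417 genes, limma called 0 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 687 genes (285 higher and 402 lower), against 921 expected by chance. That count was 1052 with the arrays quantile normalised again, 1263 with array weights, and 551 of 4301 genes without tied values, where 215 are expected. An absolute difference of at least 1 was seen in 40 genes, 16 higher and 24 lower, and all 40 had every MondoA shRNA array outside the control range. That separation was seen for 894 genes on the higher side and 954 on the lower side, where chance gives 20% of genes without ties and at most that with them. Among the 4301 genes with no tied value it was seen for 621 and 713 genes, or 31% in all, and genes are not independent of each other. The count of genes past the adjusted threshold varied with the processing. RMA gave 54% of genes the same value in at least 3 arrays. Over the 4301 genes with no tied value, a filter chosen after seeing the data that favours variable genes, 60 genes passed, all 20 genes of largest change among them, and limma's prior degrees of freedom were 5.15 against 0.56 over all genes. Without moderation 3 genes passed, and with the arrays quantile normalised again or centred 2 passed. Without control array 1 the count was 752 (1987 at unadjusted p under 0.05) and without control array 2 it was 454 (1724).

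Of the 31 gene lists, 4 passed camera, 2 higher and 2 lower in the arrays labelled MondoA shRNA. None passed when camera estimated the correlation within each list, and none passed fry's test for a shift in 1 direction. Both rest on the few residual degrees of freedom of 5 arrays, so a list can fail them although its genes shifted. Camera on ranks, which kept the preset correlation, called the same 4 lists (adjusted p from 2.95e-05 to 0.00569). The count was 1 without control array 2 and 7 without MondoA shRNA array 1, and other splits of the 5 arrays into 2 and 3 gave 1 to 10 lists by camera. The p53 target list fell, with 19 of 23 measured members below 0, 2 above, a median difference of -0.26 and a camera adjusted p of 5.98e-08 (adjusted p = 0.774 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, read 7.40 ± 0.04 in control and 6.49 ± 0.21 in MondoA shRNA arrays, a difference of -0.90. GDF15, a secreted stress cytokine, read 4.54 ± 0.14 and 3.73 ± 0.08, a difference of -0.82. The median of the list was -0.16 without control array 1. No member passed over all genes tested and 1, GDF15, passed adjusted over the list alone.

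The list of genes of maturing B lymphocytes and antigen presentation rose, with 15 of 23 members above 0, 6 below, a median difference of 0.14 and a camera adjusted p of 0.000858 (adjusted p = 0.774 with an estimated correlation). HLA-DMB, which helps to load peptides on class II molecules, differed by 0.86, and the B-cell receptor kinase gene LYN by 0.46. No member passed over all genes and 1, HLA-DMB, passed adjusted over the list alone. Without control array 2 the list no longer passed (adjusted p = 0.297). The early B-precursor list, which holds CD22, did not pass as a whole (camera adjusted p = 0.828) and its members went both ways, with 5 higher and 2 lower at an unadjusted p under 0.05. Its members included CD79A at 0.91 and the terminal transferase gene DNTT at -1.19, both chosen after their values were seen.

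The MYC targets in ribosome biogenesis rose by a small margin, with 26 of 29 members above 0, a median difference of 0.10 and a camera adjusted p of 0.00228 (adjusted p = 0.953 with an estimated correlation). The ribosome assembly genes WDR43 and NOP16 differed by 0.37 and 0.30, and 0 members passed over all genes or adjusted over the list alone. MYC itself, also chosen after its value was seen, differed by 0.02. The list no longer passed without control array 2 (adjusted p = 0.598), without MondoA shRNA array 3 (0.634) or with the replicate number as a block (0.708). The replication-dependent histone list fell, with 14 of 17 members below 0, a median difference of -0.18 and a camera adjusted p of 0.000387 (adjusted p = 0.953 with an estimated correlation). H4C3 differed by -0.45 and H3C2 by -0.07, and 0 members passed over all genes or adjusted over the list alone. Histone genes are close copies of each other and signal shared between their probe sets was not tested. Without control array 2 the list no longer passed (adjusted p = 0.262).

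**Figure D2:**
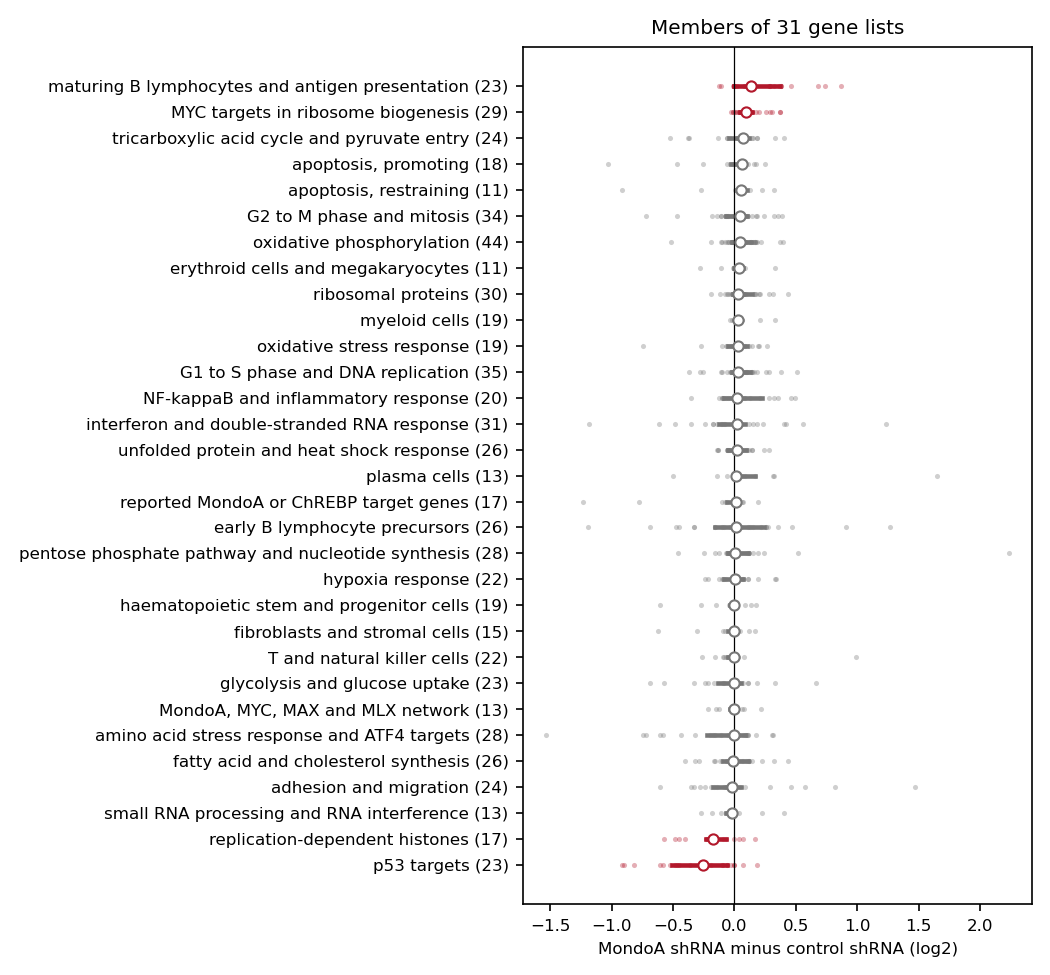
Log2 difference (MondoA shRNA minus control shRNA, horizontal axis) of the measured members of the 31 gene lists (vertical axis, number of measured members in brackets); dots are genes, bars span the middle 50% of members, circles are medians, and red marks the 4 lists that passed camera with the preset correlation. List medians ran from -0.26 for p53 targets to 0.14 for maturing B lymphocytes and antigen presentation.

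No list of metabolic genes passed camera. Glycolysis and glucose uptake (23 measured genes) had a median difference of 0.00, the tricarboxylic acid cycle with pyruvate entry (24) 0.07, oxidative phosphorylation (44) 0.04, the pentose phosphate pathway with nucleotide synthesis (28) 0.01 and fatty acid and cholesterol synthesis (26) -0.01, with both directions among the members of each. The phosphofructokinase gene PFKP at -0.69 and the glucose transporter gene SLC2A3 at -0.58 were the lowest of the glycolysis list and the enolase gene ENO2 at 0.67 was the highest. At an unadjusted p under 0.05 in limma, 3 members of that list were lower (PFKP, SLC2A3 and PFKL at -0.33) and 0 were higher. All of these genes were chosen after their values were seen. In the tricarboxylic acid cycle list 1 member, IDH2 at -0.38, passed adjusted over the list alone, and in the other metabolic lists 0 members did. The amino acid stress and ATF4 list had a camera adjusted p of 0.120, with 6 of 28 members lower and 0 higher at an unadjusted p under 0.05, and 2 passed adjusted over the list alone. The lists for unfolded protein and heat shock, oxidative stress, hypoxia, interferon and double-stranded RNA, NF-kappaB and inflammation, apoptosis (promoting and restraining), cell cycle (G1 to S phase and G2 to M phase), ribosomal proteins, adhesion and migration, and small RNA processing did not pass, nor did those for plasma cells, stem and progenitor cells, T and natural killer cells, myeloid cells, erythroid cells and megakaryocytes, or fibroblasts.

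Genes on chromosome 18 were lower as a block in the arrays labelled MondoA shRNA, a comparison made after the data were seen. All 110 chromosome 18 genes with a mean level above 5 had a negative difference, with a median of -0.42 and an SD over genes of 0.26. Without MondoA shRNA array 1, 103 of the 110 were lower, and at a mean level above 4, 124 of 131 were lower. The medians of the other autosomes and of chromosome X lay between -0.03 and 0.03. The set held BCL2, a restrainer of apoptosis, at -0.92 and PMAIP1, which encodes the apoptosis promoter NOXA, at -1.03, both chosen after their values were seen. Relative to other genes, the chromosome 18 median deviation from the 5-array mean was 0.35 and 0.16 in control arrays 1 and 2, and -0.26, -0.04 and -0.14 in MondoA shRNA arrays 1, 2 and 3. At an unadjusted p under 0.05 in limma stood 20.1% of the 264 chromosome 18 genes tested and 3.49% of other genes. Neighbouring genes are not independent replicates.

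**Figure D3:**
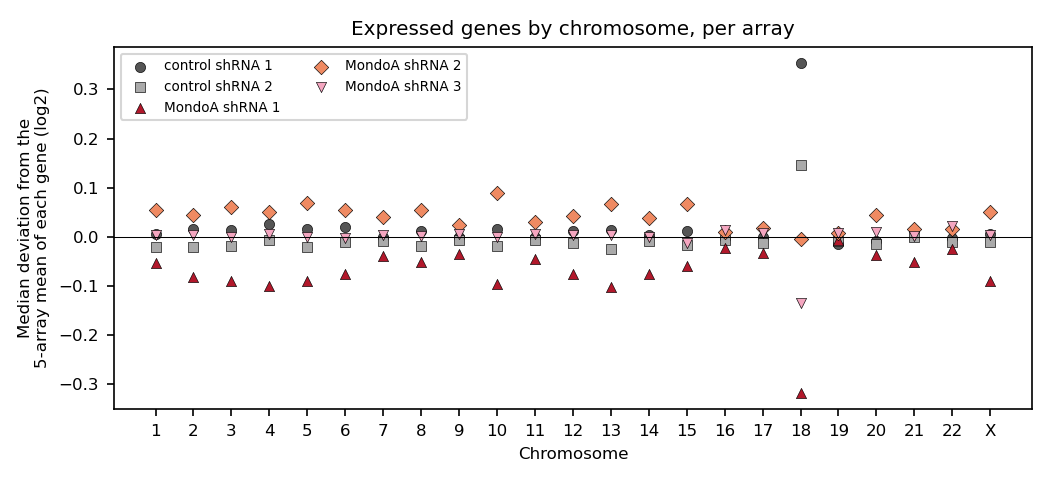
Median deviation of genes with a mean level above 5 from their 5-array mean (log2, vertical axis) for each chromosome (horizontal axis), with 1 point per array. Chromosome 18 ran from 0.35 in control array 1 to -0.32 in MondoA shRNA array 1, while the other chromosomes stayed between -0.10 and 0.09.

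The clones were close to each other. Pearson correlation across all probe sets, which are not independent replicates, ran from 0.990 (MondoA shRNA arrays 1 and 2) to 0.995 (control arrays 1 and 2). The median SD of the brighter genes was 0.05 among control and 0.13 among MondoA shRNA arrays. Over all genes it was 0.03 among control and 0.08 among MondoA shRNA arrays, and 0.04 among the latter without array 1 or without array 2. The first principal component (41.4% of variance) set MondoA shRNA arrays 1 and 2 apart, and the second (35.2%) separated the groups.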

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

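The alternatives without tied values, without chromosome 18 genes and for the chromosome 18 median were chosen after seeing the data. Across the alternatives, 0 of 473 values for the 30 named genes other than MLXIP changed sign and 28 passed the adjusted threshold, mostly without tied values. All of these genes but TXNIP and ARRDC4 had every MondoA shRNA array outside the control range, so leaving out an array could not turn their sign. Several other alternatives leave the difference itself unchanged. The count of 0 was thus largely fixed beforehand and does not measure stability. MLXIP was 0.027 with the replicate number as a block, a fit that pairs clones sharing no more than a number. That fit sets MondoA shRNA array 3 aside, so its differences equal those without that array and are no separate check. With 1 array left out, MLXIP ran from -0.065 to 0.027. The limma gene count of 0 (687 at unadjusted p under 0.05) became 2 with the arrays quantile normalised again, 2 with them centred, 3 without moderation, 60 without tied values and 0 to 752 with 1 array left out. The calls without a control array were mostly genes with 3 equal MondoA shRNA values (81.2% and 82.8%). There the remaining control is assumed to vary like the other group. The list count of 4 became 0 with an estimated correlation, 0 by fry and 1 to 7 with 1 array left out. The list count stayed at 4 with camera on ranks, which kept the preset correlation. Adjusted p values by list were as follows.

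For p53 targets they were 0.774 with an estimated correlation, 0.178 by fry and 8.9e-09 to 0.0129 with 1 array left out. For maturing B lymphocytes they were 0.774, 0.178 and 0.00101 to 0.297. For histones they were 0.953, 0.678 and 9.78e-05 to 0.262. For MYC targets they were 0.953, 0.742 and 8.45e-06 to 0.634, and 0.708 with the replicate block. The estimated correlation was 0.095 for p53 targets, 0.039 for maturing B lymphocytes, 0.288 for histones and 0.374 for MYC targets, against the preset 0.01. In the amino acid stress list it was -0.0035, below the preset, yet the camera p rose from 0.0193 to 0.0779. A higher correlation is thus not needed for the camera p to rise. Camera with an estimated correlation also rests on the few residual degrees of freedom of these arrays, which by itself can raise a p value. For the lists that lost their call, the part of the higher correlation and that of the degrees of freedom were not separated. Fry's mixed test, which counts members moving in either direction, gave adjusted p values of 0.00352 for p53 targets and 0.00629 for maturing B lymphocytes. It gave 0.0333 for histones and 0.659 for MYC targets. Lists that did not pass camera also passed the mixed test, among them amino acid stress (6.33e-06), the tricarboxylic acid cycle (0.000549) and early B precursors (0.00251). Another was T and natural killer cells (0.00129), with 16 of 22 members below the median gene level. Passing the mixed test was thus not particular to p53 targets or maturing B lymphocytes. The chromosome 18 median relative to other genes ran from -0.52 to -0.33 with 1 array left out. Signal over background was not assessed.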

Other observations

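The tests on MLXIP, TXNIP and tied values, on the other chromosomes, the share of lower genes and the blocks of chromosome 18, and on the chromosomes and left-out arrays of the p53 list were chosen only after the result was seen. Beyond the fixed rule, several lower genes belonged to the amino acid stress list: the cystine transporter gene SLC7A11 at -0.74, the glutathione-degrading enzyme gene CHAC1 at -0.72, the secreted glycoprotein gene STC2 at -0.60 and the stress-induced SESN2 at -0.58, beside DDIT3 at -1.53. ATF4 itself differed by -0.02 and the asparagine synthetase gene ASNS by 0.17, so the list did not move as one. LY86, which encodes the partner protein of CD180, differed by 1.21. The interferon list was also divided, with XAF1 at -1.18 and BST2 at 1.24. In the early B-precursor list, the transcription factor genes IKZF3 and TCF3 differed by 0.47 and 0.25, while SOX4 and LEF1 differed by -0.47 and -0.33. All of these genes were chosen after their values were seen.

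MLXIP did not separate the groups. MLXIP spanned 0.183 log2 units over the 5 arrays, so no exchange of labels among them gives a difference beyond that, but a larger one hidden by the summarised values stays open. The lower end of the 95% interval for TXNIP was -0.331, so a fall by 1.5-fold or more lay outside the interval for the summarised values under these culture conditions. TXNIP read exactly the same in MondoA shRNA arrays 1 and 2 (8.91), so the values may be drawn together and a larger fall of its RNA stays open. Compression by median polish stays open: 35.7% of genes of a similar level had a value shared by at least 3 arrays, MLXIP among them. A change of MondoA protein without a change of its RNA was not tested.

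For chromosome 18, whole-array scaling is excluded, since the largest shift of any other chromosome was 0.0278 log2 units, and regulation of a minority of genes is excluded, since 100% of the 110 genes were lower (103 without MondoA shRNA array 1, and 124 of 131 at a mean level above 4). Each of 5 blocks of neighbouring genes was lower, the least by -0.365, so a candidate explanation is a different dose of the whole chromosome between clones, for instance an extra copy in part of the cells. The step from 3 to 2 copies gives 0.585 log2 units, against 0.61 between control array 1 and MondoA shRNA array 1 relative to other genes. That pair was the widest and was picked after the values were seen, so the match is no test of this explanation. The deviations were 0.35 and 0.16 in control arrays 1 and 2, and -0.26, -0.04 and -0.14 in MondoA shRNA arrays 1, 2 and 3. If dose alone set them, such graded values would need clones of mixed cells. Other sources of the grading were not tested, and no copy number was measured here. Of the 10 splits of the arrays into 2 and 3, only 1, the real split, gave a shift as large (-0.42, highest other 0.34). Chromosome 18 was picked after the real split had been seen, which favours that split, so its rank is no test. Besides, 10 splits are too few for a share under 0.05.

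For the p53 targets, 0 list members lie on chromosome 18, so the list does not carry that shift through its own members, and an indirect effect of chromosome 18 genes was not tested and stays open. The direction did not rest on a single array, since 18 or 19 of the 23 members were below 0 whichever array was left out. The size did move, with a median of -0.161 without control array 1, the array whose loss moved it most towards 0, and -0.373 without control array 2. A single array as part of the cause stays open. The SD over members was 0.31, wider than the median over all 5 arrays, so it cannot decide this. Of the 10 splits, 2 gave a median as large (real -0.26, highest other 0.29), and 10 splits are too few for a share under 0.05. The larger one set MondoA shRNA arrays 1 and 3 against the rest, and control array 1 with MondoA shRNA array 2 against the rest gave -0.25. Other splits called up to 10 lists by camera and up to 771 genes at unadjusted p under 0.05, against 4 and 687 for the real split, while 40 genes had an absolute log2 difference of at least 1 in the real split and 19 at most in any other, and whether the p53 list follows that label stays open.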
